A study of Mus musculus with 9 samples.

How the data were processed

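Polyadenylated RNA of mouse liver was sequenced in 9 libraries, 3 labelled control, 3 model and 3 treated. Per the labels, RNA was purified with TRIzol and libraries were prepared with an Illumina protocol. The series title names liver damage induced by gefitinib, an inhibitor of the tyrosine kinase of the epidermal growth factor receptor. The titles call the samples mouse liver cells and the source is given as liver, so it is not stated whether RNA came from whole tissue or from isolated cells, and livers here stand for these samples. The labels give no dose, time, sex, strain or batch, and they do not say what the treated mice received. They do not say that the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, part of which can be technical.

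HISAT2, a spliced aligner, is the 1 program named in the submitters' processing notes, without a version. The quantifier, its strand setting and the annotation are not given in the sources used here. The authors deposited estimated counts per gene and per transcript, and FPKM, fragments per kilobase scaled to library size, per gene and per transcript, per the file headers. The estimated counts deposited by the authors are whole numbers. In at least 99.38% of transcripts per library, the count equalled FPKM times transcript length times 1 constant of that library, rounded up, and 99.993% of gene counts equalled the sum of their transcripts' counts. They are therefore estimates from coverage and not a direct tally of reads. No further rounding was needed. Reads of overlapping genes and of near-identical gene copies were divided by that estimation, so values of such genes are uncertain. Coordinates are those in the files. Of the 27945 gene IDs with a count, 27859 were in GENCODE M21, an annotation of the mouse build GRCm38, and 25083 had the same start and end there, so the coordinates are GRCm38.

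Library totals ran from 56440871 to 60665156 estimated counts, and 20579 to 21441 genes per library had a count. A single count is thus worth about the same in each library. Counting intervals and floors given in the text cover counting error only, since PCR copies were not marked with molecular identifiers. The floor for a group without counts was 3 counts per library. Intervals are 95% binomial intervals by the exact method, which treats the estimated counts as tallies of reads, so they are approximate.

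Gene counts were tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F tests with robust dispersions in 1 fit over all 9 libraries, with TMM scaling. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 18113 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, within each of 3 comparisons. Levels are CPM, counts scaled to library size, on TMM-scaled library sizes, given as mean ± SD of 3 libraries, and fold changes with standard errors (SE) are those of the fit. Before the data were examined, 52 gene lists of liver functions and of cell type markers were written, of which 50 had at least 5 genes tested. Of their 1419 entries, 1378 matched a gene with a count. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move on balance 1 way. Other splits of the libraries also gave many lists at the preset correlation, so that members called are given for each list together with the adjusted p at the estimated correlation. Member counts are adjusted over all genes tested unless they are called adjusted over the list alone.

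Named genes followed a rule set before the data were examined. Per comparison these were the 5 rising and 5 falling called genes with the largest fold change, libraries that did not overlap, an official symbol and at least 5 CPM in the higher group. Added to them were the 2 called members with the smallest p in each of the 10 lists with most called members. Egfr, Cyp3a11, Cyp1a1, Cyp2d22 and Alb were named in the comparisons that involve the model group, whatever their test. Named as well were the 5 genes per direction with the smallest product of p-values among those called in opposite directions in model versus control and treated versus model. A few genes that this rule names are not reported here.

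The procedure was tested on simulated counts with 200 planted changes per comparison. In the simulation of model versus control, over 17436 genes, 29 of 50 genes changed 2-fold and 44 of 50 genes changed 4-fold were called in the right direction, with 9 false calls. In that of treated versus model, over 17449 genes, the numbers were 18 and 40 of 50, with 6 false calls, and in that of treated versus control, over 17463 genes, 27 and 42 of 50, with 2 false calls. A planted list was called in each simulation, and each of the 49 unchanged lists stayed above the threshold. Simulated genes were independent and the unchanged lists were random genes, so this does not test lists whose genes vary together. In the real libraries, other splits called 4 to 26 of 50 lists at the preset correlation.

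Alternatives were RLE and upper-quartile scaling, no filter or a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of the 2 groups compared alone, a replicate block, leaving out each library, stricter thresholds, leaving out the 20 genes of highest count, and limma on the authors' deposited FPKM as log2(FPKM + 1) or log2(FPKM + 0.1) at a mean of at least 1 FPKM, or without that filter. List member counts without model replicate 1 were added after the data were examined. Within groups, libraries differed far beyond sampling noise (chi-square per degree of freedom 74.8 to 155), so each counted as 1 sample.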

Results

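Liver RNA of 9 mouse libraries was compared between a control group, a group labelled model and a group labelled treated, with n = 3 libraries each. From the series title, the model concerns liver damage by gefitinib, and the comparisons ask how model livers differ from control livers and where treated livers stand relative to both. Totals were 56440871 to 60665156 estimated counts per library. On the first principal component, with 32.1% of the variance, the control libraries lay at -70.4 to -54, the model libraries at -17.8 to -6.9 and the treated libraries at 64.9 to 81.4. Transcripts of skeletal muscle were present in part of the libraries. The 7 skeletal muscle markers of the fixed list summed to 101 to 154 CPM in model replicate 1 and the 3 treated libraries, and to at most 1.06 CPM in the other 5 libraries.

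**Figure D1:**
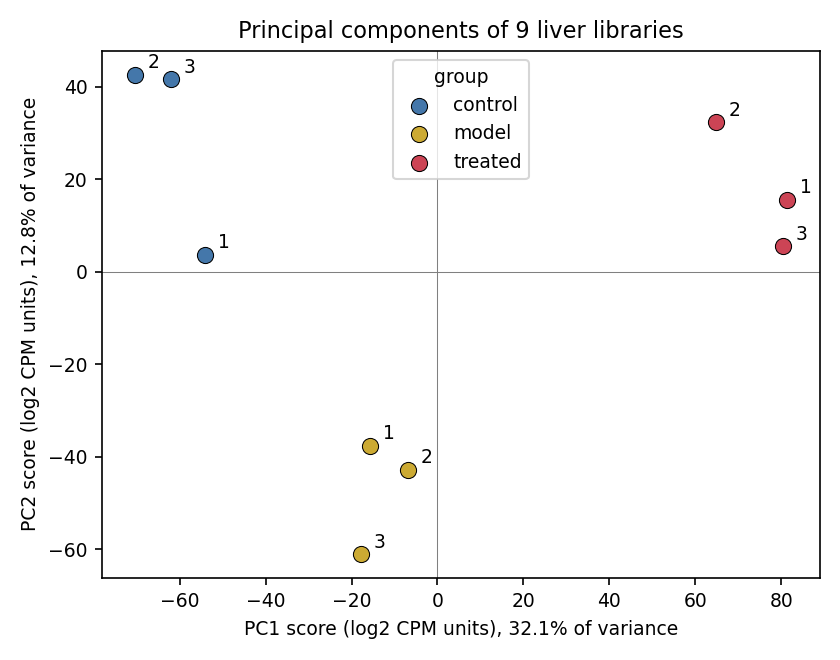
Scores of the 9 libraries on the first (x axis, 32.1% of the variance) and second (y axis, 12.8%) principal component of log2 CPM over the 18113 genes tested, each point being 1 library marked by its replicate number and coloured by group. The treated libraries lie at 64.9 to 81.4 on the first component, beyond the model libraries as seen from the controls.

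In model compared with control livers, 12 endothelial transcripts fell, and 3 macrophage and 4 acute phase transcripts rose. Of the 20 endothelial markers tested, 12 were called, each of them lower, and 19 were lower when adjusted over the list alone. The list passed camera (adjusted p = 5.18e-47) and kept an adjusted p = 0.0341 with an estimated correlation. It was the 1 list of this comparison that did. Markers of hepatic stellate cells lay lower too, with a median log2 fold change of -0.56 over 18 markers (camera adjusted p = 3.71e-05, and adjusted p = 0.285 with an estimated correlation), but no marker was called over all genes, and 5 were lower and 1 higher adjusted over the list alone. Pecam1, an adhesion molecule of endothelial cells (chromosome 11, 106654217 to 106750628, GRCm38), fell from 15.8 ± 2.37 to 5.37 ± 0.544 CPM (log2 fold change -1.55, SE 0.18, adjusted p = 0.0068). Stab2, a scavenger receptor of liver sinusoidal endothelium, fell from 108 to 47.9 ± 6.70 CPM (log2 fold change -1.17, SE 0.14, adjusted p = 0.0068). Lyve1, a hyaluronan receptor of sinusoidal and lymphatic endothelium, fell 4.28-fold to 1.62 ± 0.840 CPM (adjusted p = 0.0267), a call that was lost with 5 of 17 alternatives, among them leaving out any single control library.

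Macrophage markers with a call were higher, namely 3 of 23 tested (5 adjusted over the list alone). Gpnmb, a glycoprotein of lipid-laden and phagocytic macrophages, rose 4.78-fold from 1.56 ± 0.275 to 7.47 ± 2.25 CPM (adjusted p = 0.00851), and Mpeg1, a pore-forming protein of macrophages, rose 1.81-fold (adjusted p = 0.0112). The other was Cd68, named after its values were seen. For this list the adjusted p was 0.372 with an estimated correlation. Mmp12, the macrophage metalloelastase, rose 10.1-fold (adjusted p = 0.015) and Lilr4b rose from 3.30 ± 0.766 to 22.9 ± 1.37 CPM (log2 fold change 2.79, SE 0.16, adjusted p = 4.71e-05). Of the 31 acute phase genes tested, 4 were called, each of them higher, and 12 were higher and 1 lower when adjusted over the list alone (adjusted p = 0.285 with an estimated correlation). Haptoglobin (Hp) rose 1.78-fold from 3579 ± 449 to 6374 ± 456 CPM (adjusted p = 0.0128) and Steap4, a metalloreductase, rose 1.67-fold (adjusted p = 0.0282). Saa2, a serum amyloid A gene with close paralogs, rose 5.78-fold (adjusted p = 0.0446), and Hpx was the other member called, named here after its values were seen. Saa2 lost its call in 9 and Steap4 in 6 of 17 alternatives, both of them without any 1 of the 3 model libraries, and Hp lost it without model replicate 2 or 3 (highest adjusted p = 0.0664). Without model replicate 1, 2 acute phase genes were called. Mmp12 was not called without control replicate 2 (adjusted p = 0.0503), nor Gpnmb with limma-voom (adjusted p = 0.0671).

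Smaller groups had few calls. Of 43 autophagy and lysosome genes, 3 were called and higher (4 adjusted over the list alone), with Atp6v0d2, a subunit of the vacuolar proton pump, at 2.55-fold (adjusted p = 0.0112) and Hexa, a lysosomal hexosaminidase, at 1.59-fold (adjusted p = 0.0412, and an adjusted p of 0.285 with an estimated correlation for the list). The other was Ctsd, named after its values were seen. Hexa lost its call in 11 and Ephx1 in 9 of 17 alternatives, both of them without any 1 of the 3 model libraries. Ugdh and Ephx1, enzymes that the NRF2 and phase II lists share, rose 2.01-fold and 1.59-fold (adjusted p = 0.0157 and 0.0391), the 2 called members of 29 NRF2 targets and of 33 phase II genes (adjusted p = 0.285 with an estimated correlation for each list). Adjusted over the list alone, 12 NRF2 targets were higher and 2 lower, and 10 phase II genes were higher and 2 lower. Of 31 ferroptosis and iron handling genes, 2 were called (3 higher and 2 lower adjusted over the list alone), Hfe at 1.68-fold (adjusted p = 0.0128) and Acsl4 at 1.76-fold (adjusted p = 0.0445). Acsl4 lost its call in 8 of 17 alternatives, among them without any 1 of the 3 control libraries. Among 29 glycolysis and gluconeogenesis genes, Pklr, the liver pyruvate kinase, rose 2.02-fold (adjusted p = 0.0137) and Ppp1r3b, a glycogen-targeting phosphatase subunit, fell 2.82-fold (adjusted p = 0.0152). These 2 lists did not pass camera (adjusted p = 0.22 and 0.92), and the second had a median log2 fold change of 0.07 with a mean of -0.08 (2 members higher and 2 lower adjusted over the list alone). Calls ended without single control or model libraries for Ugdh, Pklr, Ppp1r3b and Hfe too (highest adjusted p = 0.0657, 0.0583, 0.0594 and 0.0617). Without model replicate 1, 1 autophagy and lysosome gene and 4 phase II genes were called.

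Among 40 genes of EGFR ligands and feedback, 1 was higher and 3 were lower (1 and 4 adjusted over the list alone, camera adjusted p = 0.16). Ccnd1, a cyclin of the first gap phase, rose 3.31-fold (adjusted p = 0.0152) and Spry4, a feedback inhibitor of receptor tyrosine kinases, fell 4.21-fold (adjusted p = 0.0267). The other lower members were Fos and Phlda1, the latter named after its values were seen. Without model replicate 1, 1 member was lower. Ccnd1 lost its call without control replicate 2 or 3 or model replicate 2 or 3 (highest adjusted p = 0.0642), and Spry4 without control replicate 2 or 3 or model replicate 2 (highest adjusted p = 0.114). Egfr itself, the target of gefitinib, was at 378 ± 115 CPM in control and 596 ± 128 CPM in model livers, which was not past the threshold (fold 1.57, adjusted p = 0.305). Cyp3a11, Cyp2d22 and Alb differed by 1.11-fold, 0.96-fold and 1.01-fold, within the spread between libraries (adjusted p = 0.772, 0.926 and 0.976), and Cyp1a1 was at 0.583 ± 0.367 and 1.95 ± 1.48 CPM (adjusted p = 0.251).

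Of the 23 circadian clock genes, 4 were called, each of them lower. Arntl and Npas2, which encode partner subunits of clock transcription factors, fell 2.88-fold (adjusted p = 0.0128) and 7.20-fold (adjusted p = 0.0128). The others were Clock and Rora, named after their values were seen. Without model replicate 1, 1 clock gene was called. Arntl lost its call without model replicate 1 or 2 (highest adjusted p = 0.0584) and Npas2 without model replicate 2 or 3 (highest adjusted p = 0.0678). The list as a whole moved both ways, with 8 members higher and 7 lower adjusted over the list alone, a median log2 fold change of 0.30 and a camera direction that was down (adjusted p = 0.982).

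The largest fold changes of the remaining named genes were those of Gemin4 and Igsf23. Gemin4, of the SMN complex that assembles spliceosomal ribonucleoproteins (chromosome 11, 76210571 to 76217664), had 5 counts over the 3 control libraries against 1173 over the model libraries, a ratio of 219 (95% interval 93.8 to 677). It lies inside the span of Glod4 on the same strand, and the sum of both was 44.7 ± 2.62 CPM in control and 47.5 ± 1.81 CPM in model livers, so the division of reads between them is uncertain. Igsf23 fell from 8.61 ± 4.56 to 0.217 ± 0.166 CPM (adjusted p = 0.0155), a call lost with limma-voom and without model replicate 2 (highest adjusted p = 0.231). Zbtb16, a zinc finger transcription factor, fell 7.06-fold from 37.2 ± 16.2 to 5.26 ± 0.869 CPM (adjusted p = 0.0068), Plpp1, a lipid phosphatase, 5.23-fold (adjusted p = 0.0112) and Adgrv1, an adhesion receptor, 9.15-fold (adjusted p = 0.0372, a call lost in 10 of 17 alternatives).

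In total, 94 of 18113 genes were higher and 108 lower in model than in control livers, of which 55 and 74 changed at least 2-fold. With camera at its preset correlation, 12 lists were up and 5 down among 50, of which 1 passed with an estimated correlation, fry called 2, and another split of these 6 libraries gave 23. The gene counts depended on single libraries. They were 28 and 26 without model replicate 2, 34 and 46 without model replicate 3, 63 and 46 without model replicate 1, 40 and 52 without control replicate 2, and 40 and 42 without control replicate 3.

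**Figure D2:**
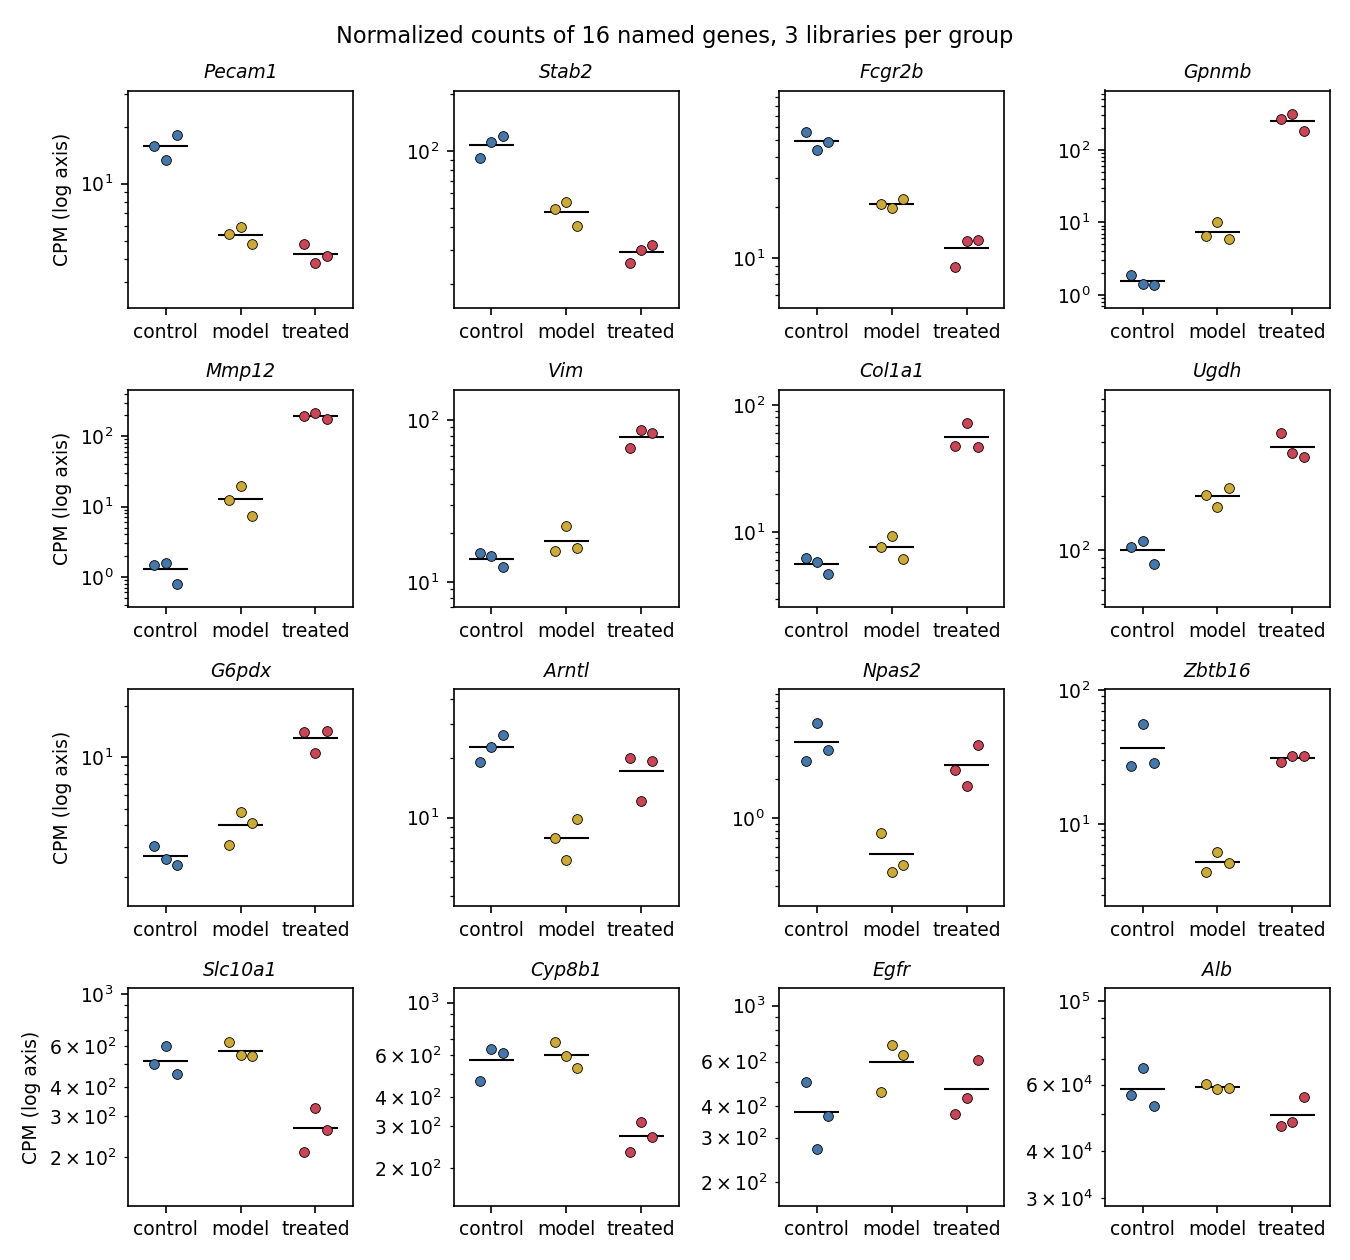
CPM on log axes of 16 named genes in the control, model and treated libraries (x axis), each point being 1 library and each line the group mean (n = 3). Gpnmb averaged 1.56, 7.47 and 254 CPM in control, model and treated livers, Pecam1 15.8, 5.37 and 4.25 CPM, and Zbtb16 37.2, 5.26 and 31.1 CPM.

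In treated compared with model livers, 5 lists passed with an estimated correlation, those of extracellular matrix, inflammation, p53 targets, EGFR ligands and feedback, and the integrated stress response. Of 45 genes of extracellular matrix and fibrosis, 26 were called, each of them higher (36 adjusted over the list alone), with a median log2 fold change of 1.36 and an adjusted p = 0.0378 with an estimated correlation. Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042), rose 7.23-fold from 7.68 ± 1.61 to 55.6 ± 14.1 CPM (adjusted p = 6.8e-05). Vim, the intermediate filament vimentin, rose from 17.9 ± 3.60 to 78.8 CPM (log2 fold change 2.14, SE 0.16, adjusted p = 6.8e-05). Mmp13, a collagenase, rose 24.0-fold to 13.4 ± 3.57 CPM (adjusted p = 0.000184).

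Of 32 inflammatory cytokines and chemokines, 11 were called, each higher (15 adjusted over the list alone, adjusted p = 0.0378 with an estimated correlation). Il1rn, the interleukin-1 receptor antagonist, rose 6.39-fold (adjusted p = 0.000198) and Cxcl2, a chemokine for neutrophils, rose from 0.174 ± 0.0616 to 2.21 ± 0.530 CPM (adjusted p = 0.00115). Gpnmb rose a further 34.0-fold to 254 ± 68.1 CPM (adjusted p = 5.59e-05). Of 39 interferon response genes, 9 were called and higher (18 adjusted over the list alone), with Oas1a, of a family of close paralogs, at 4.91-fold and Usp18 at 2.35-fold (adjusted p = 0.00173 and 0.00898). The interferon list had an adjusted p = 0.384 with an estimated correlation.

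Of 30 p53 and DNA damage targets, 10 were called, each higher (14 adjusted over the list alone, adjusted p = 0.0378 with an estimated correlation). Trp53inp1 rose 5.44-fold (adjusted p = 0.000347) and Btg2, an antiproliferative gene, 5.66-fold (adjusted p = 0.000649). Of 29 NRF2 targets, 13 were called, each higher (20 adjusted over the list alone), with an adjusted p = 0.215 with an estimated correlation. G6pdx and Pgd, enzymes of the oxidative pentose phosphate pathway, rose 3.23-fold and 3.66-fold (adjusted p = 0.00125 and 0.0015). Slc7a11, the cystine transporter, averaged 0.159 ± 0.116 CPM in model and 9.46 ± 9.06 CPM in treated livers (adjusted p = 0.0125), a call lost with the replicate block, with limma-voom and without model replicate 3 (highest adjusted p = 0.205). Of 27 genes of the integrated stress response and ATF4 targets, 7 were higher and 1 lower (12 and 2 adjusted over the list alone, adjusted p = 0.0378 with an estimated correlation). The lower member was Shmt2, named after its values were seen, and without model replicate 1 the numbers were 6 higher and no lower member.

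Of 40 genes of EGFR ligands and feedback, 15 were higher and 2 lower (18 and 3 adjusted over the list alone, adjusted p = 0.0378 with an estimated correlation). Dusp6, a phosphatase of ERK, rose from 11.6 ± 2.49 to 47.6 CPM (log2 fold change 2.04, SE 0.21, adjusted p = 0.000371) and Fos, an immediate early transcription factor, 11.4-fold to 7.63 ± 1.71 CPM (adjusted p = 0.00046). The 2 lower members were Erbb3 and Lrig3, named after their values were seen. Egfr was at 469 ± 122 CPM in treated livers (fold 0.787 over model, adjusted p = 0.479). Among 31 cell death genes, 7 were higher and 2 lower, the same numbers as adjusted over the list alone. Bcl2l1, which encodes an antiapoptotic protein, rose 2.85-fold (adjusted p = 0.000525), and Bik, which encodes a proapoptotic protein, fell 3.76-fold (adjusted p = 0.000532). The other lower member was Bad, which also encodes a proapoptotic protein and was named after its values were seen. The cell death list did not pass camera (adjusted p = 0.12).

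Hepatocyte markers had 3 of 19 members lower, Serpina1a, Serpina1b and Serpina1c, which are close paralogs, and 1 higher, Hnf4a, all named after their values were seen. Adjusted over the list alone, 7 were lower and 2 higher (camera adjusted p = 0.0392, direction down, and adjusted p = 0.518 with an estimated correlation), and without model replicate 1, 1 was lower. Among lists with falling members, 12 of 40 genes of fatty acid oxidation and PPARalpha targets were called, each lower. Adjusted over the list alone, 21 were lower and 2 higher, and the adjusted p was 0.384 with an estimated correlation. Decr2 and Acaa1a, a peroxisomal thiolase, fell by 0.74 and 0.58 on the log2 scale (adjusted p = 0.0083 and 0.0129), and Acaa1a lost its call without treated replicate 1 or 3 (highest adjusted p = 0.0532). Of 26 bile acid genes, 7 were lower and 2 higher (11 and 2 adjusted over the list alone, adjusted p = 0.384 with an estimated correlation). Cyp8b1, the sterol hydroxylase for cholic acid, fell 2.21-fold from 602 ± 77.5 to 273 ± 39.6 CPM (adjusted p = 0.00174), and Slc10a1, the bile acid uptake transporter, 2.15-fold (adjusted p = 0.00249). The higher members were Slc10a2 and Abcc4, named after their values were seen. Of 35 urea cycle and amino acid genes, 9 were called, each lower (17 lower and 2 higher adjusted over the list alone, adjusted p = 0.367 with an estimated correlation). Gls2, the liver glutaminase, fell 2.05-fold (adjusted p = 0.00103) and Slc38a3, a glutamine transporter, 1.65-fold (adjusted p = 0.0027). Of 20 endothelial markers, 8 were called, each lower (10 adjusted over the list alone, adjusted p = 0.328 with an estimated correlation), and 3 without model replicate 1.

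Igsf23 rose from 0.217 ± 0.166 CPM in model to 27.1 ± 7.91 CPM in treated livers (adjusted p = 0.00121), and Elovl7, a fatty acid elongase, from 0.525 ± 0.526 to 15.5 ± 12.5 CPM (adjusted p = 0.0127), a call lost with limma-voom and without model replicate 1 (highest adjusted p = 0.11). Among genes that met the naming rule, the largest falls were in Clec2h (8.33-fold, adjusted p = 0.0105), Vmn1r90 (7.98-fold, adjusted p = 0.000327), Hamp2, a hepcidin gene with a close paralog (7.48-fold, adjusted p = 0.00885, but 0.0728 with limma-voom), Nrep (log2 fold change -2.59, adjusted p = 0.00509) and the clock gene Per3 (5.37-fold, adjusted p = 0.0375). Per3 lost its call in 7 of 17 alternatives, among them without any 1 of the 3 model libraries. Cyp3a11, Cyp2d22 and Alb were at 0.895-fold, 0.759-fold and 0.842-fold of the model level (adjusted p = 0.62, 0.162 and 0.242), and Cyp1a1 was at 2.87 ± 0.743 CPM (adjusted p = 0.644).

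In total, 943 genes were higher and 805 lower in treated than in model livers, 531 and 219 of them at least 2-fold, and 16 lists were up and 12 down at the preset correlation, 5 of which passed with an estimated correlation. Skeletal muscle transcripts stood in each treated library and in 1 of 3 model libraries. Without that library, model replicate 1, 525 genes were higher and 357 lower, with 18 members called in the matrix list, 6 in the inflammatory, 8 in the NRF2, 7 in the p53, 2 in the fatty acid oxidation and 4 in the urea cycle list, in the same directions. Members called were then 4 in the interferon list, 3 in the endothelial list, 2 higher and 4 lower in the bile acid list, 2 higher and 1 lower in the cell death list, and 10 higher and 1 lower in the EGFR list. Of 12 skeletal and smooth muscle markers, 7 were called higher without model replicate 1 (median log2 fold change 7.03). Model replicates 2 and 3 had 0.733 and 0.63 CPM of the skeletal muscle markers. Without model replicate 1, muscle transcripts thus went fully with the treated group. That setting alone therefore cannot separate the calls that stayed from muscle tissue. Model replicate 1 held 154 CPM of these markers, against 135, 101 and 112 CPM in treated replicates 1, 2 and 3. With all libraries, 0 of 25 muscle genes were called in treated versus model livers, so the calls of the full fit did not follow these genes. The 25 genes made up at most 0.0322% of counts in the 4 libraries. Counts were 540 and 432 without model replicate 3, 578 and 417 without treated replicate 1, and 617 and 476 without treated replicate 3.

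**Figure D3:**
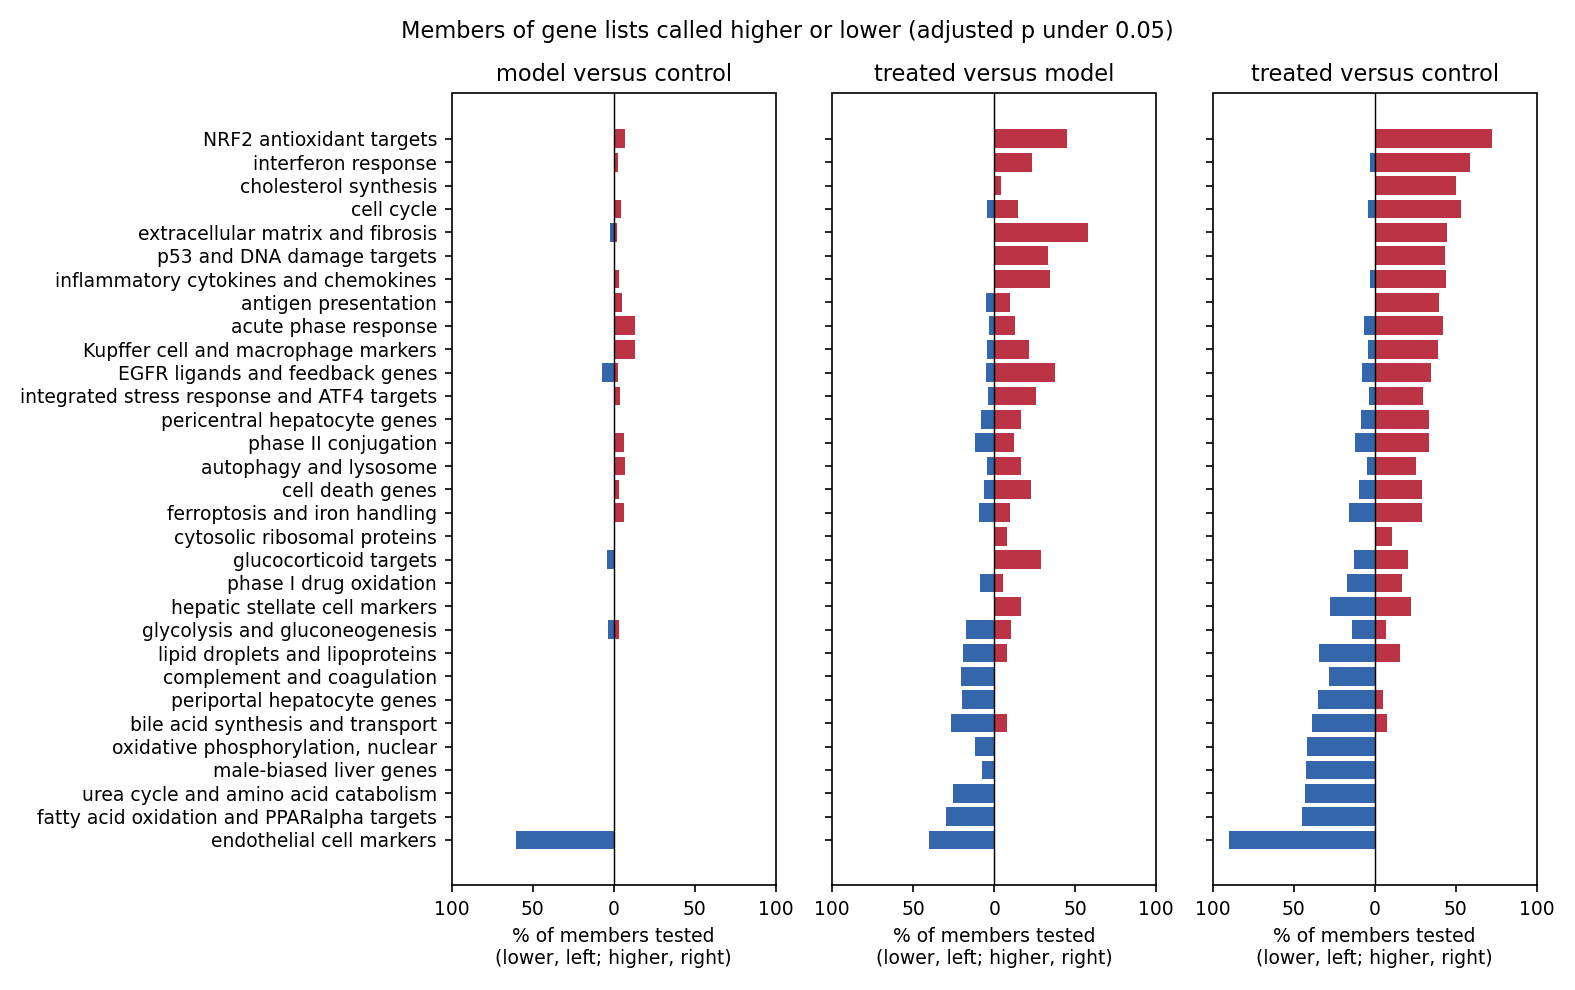
Share of the tested members of 31 gene lists (y axis) called higher (red, to the right) or lower (blue, to the left) in each comparison, in percent of the members tested (x axis), for lists with at least 8 called members in any comparison. Of 20 endothelial markers, 12, 8 and 18 were lower in model versus control, treated versus model and treated versus control.

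Treated compared with control livers differed in more genes than either comparison with the model group, 1696 higher and 1535 lower, 912 and 542 of them at least 2-fold. The counts were 1170 and 999 without treated replicate 1. Of 20 endothelial markers, 18 were called, each lower, as when adjusted over the list alone. Fcgr2b, an Fc receptor of sinusoidal endothelium, fell 4.35-fold from 49.8 ± 6.18 to 11.4 ± 2.23 CPM (adjusted p = 2.27e-05) and Stab2 3.68-fold to 29.4 ± 3.22 CPM (adjusted p = 3.05e-05). This list had an adjusted p = 0.0677 with an estimated correlation, and no list passed in that setting although 29 passed camera at the preset correlation and 28 passed fry.

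Of 47 cell cycle genes, 25 were higher and 2 lower (35 and 2 adjusted over the list alone, adjusted p = 0.241 with an estimated correlation). Ccnd1 rose 7.80-fold from 8.12 ± 2.66 to 63.4 ± 13.9 CPM (adjusted p = 0.000116). Tk1, a thymidine kinase of the DNA synthesis phase, fell 2.99-fold (adjusted p = 0.000353), and it overlaps Afmid on the other strand. The other lower member was E2f8, named after its values were seen. Of 29 NRF2 targets, 21 were called, each higher (23 adjusted over the list alone, adjusted p = 0.0995 with an estimated correlation), with Ugdh at 3.77-fold and G6pdx at 4.91-fold (adjusted p = 5.09e-05 and 0.000122). Of 45 matrix genes, 20 were called, each higher (22 adjusted over the list alone, adjusted p = 0.0995 with an estimated correlation). Col1a1 rose 9.92-fold (adjusted p = 1.36e-05) and Vim 5.66-fold (adjusted p = 1.18e-05).

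Of 39 interferon response genes, 23 were higher and 1, Iigp1, lower (30 and 1 adjusted over the list alone, adjusted p = 0.175 with an estimated correlation), with Usp18 at 4.94-fold and Oas1a at 7.61-fold (adjusted p = 0.000168 and 0.00025). Of 31 acute phase genes, 13 were higher and 2, Hamp2 and Serpina3m, lower (15 and 2 adjusted over the list alone, adjusted p = 0.267 with an estimated correlation), with hemopexin (Hpx) at 2.77-fold and Steap4 at 3.67-fold (adjusted p = 0.000412 and 2.05e-05). Of 32 inflammatory genes, 14 were higher and 1, Cxcl13, lower (19 and 1 adjusted over the list alone, adjusted p = 0.0936 with an estimated correlation), with Il1rn at 7.48-fold and Tlr2, a receptor for bacterial lipopeptides, at 6.07-fold (adjusted p = 5.09e-05 and 5.92e-05). Of 40 genes of EGFR ligands and feedback, 14 were higher and 3, Spry4, Phlda1 and Erbb3, lower (16 and 4 adjusted over the list alone, adjusted p = 0.136 with an estimated correlation), with Dusp5 at 5.37-fold (adjusted p = 0.000303). Iigp1, Serpina3m, Cxcl13, Phlda1 and Erbb3 were named after their values were seen.

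Of 19 hepatocyte markers, 6 were called, each lower (7 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -0.23 (camera adjusted p = 0.0219, and adjusted p = 0.482 with an estimated correlation). Of 60 nuclear genes of oxidative phosphorylation, 25 were called, each lower (37 adjusted over the list alone, adjusted p = 0.349 with an estimated correlation). Ndufb9, of complex I, fell 1.71-fold and Sdhb, of complex II, 1.46-fold (adjusted p = 0.00203 and 0.00298). The median log2 fold change of this list was -0.304 with RLE and -0.342 with upper-quartile scaling. On FPKM, which carry no scaling for composition, the median of all genes was 0.16, against -0.009 with TMM. The size of small falls such as these therefore depends in part on that scaling. Of 40 genes of fatty acid oxidation and PPARalpha targets, 18 were called, each lower (28 adjusted over the list alone, adjusted p = 0.294 with an estimated correlation).

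Among genes that met the naming rule, the largest rises were in H2-M2, a nonclassical class I histocompatibility gene, and Sprr1a, of the cornified envelope. H2-M2 had 4 counts over the control and 1517 over the treated libraries, a ratio of 311 (95% interval 121 to 1142), and Sprr1a 4 and 1459 counts, a ratio of 299 (117 to 1098). Sprr1a was not called with limma-voom (adjusted p = 0.0809). Gpnmb rose 163-fold (adjusted p = 5.16e-06) and Mmp12 152-fold to 195 ± 21.4 CPM (adjusted p = 9.77e-05). Gemin4 had 5 and 1426 counts, a ratio of 234 (99.9 to 721), with the same uncertainty from Glod4. The major urinary protein genes Mup7, Mup21 and Mup1, near-identical copies whose reads are hard to assign, fell 24.3-fold, 21.4-fold and 16.8-fold (adjusted p = 0.043, 0.00982 and 0.0496), Adgrv1 20.6-fold (adjusted p = 0.00163) and Hamp2 14.9-fold (adjusted p = 0.00151). Cyp1a1, outside the rule in this comparison and chosen after its values were seen, was 4.91-fold higher in treated than in control livers (adjusted p = 0.0324). Mup1 lost its call in 11 and Mup7 in 10 of 17 alternatives, both of them without any 1 of the 3 model libraries. Skeletal muscle transcripts stood in each treated and in 0 of 3 control libraries, so they cannot be separated from the group in this comparison. Of 12 skeletal and smooth muscle markers, 7 were called higher without model replicate 1 (median log2 fold change 5.87). With all libraries, 1 of 25 muscle genes was called in this comparison. Model replicate 1 is in neither group here but enters the fit over all 9 libraries. There its muscle transcripts, unlike those of the other model libraries, add to the spread, so the full fit can miss such genes.

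The comparisons of model with control and of treated with model livers share the model libraries, and the genes called in both were counted by direction. Of these genes, 41 moved in opposite directions, 13 of them higher in model and lower in treated and 28 the reverse, while 49 moved in the same direction, 37 higher and 12 lower in both. Independent lists of these lengths would share 9.8 and 9.69 genes. Of the 202 genes called in model versus control, 153 were called in the same direction in treated versus control and 2 in the opposite direction, but both comparisons use the same control libraries, which favours the same direction, and no value without a group effect was computed for this pair.

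Among the opposite genes, Gpr146 rose 1.89-fold in model livers and fell 3.06-fold in treated livers (adjusted p = 0.00791 and 6.8e-05), Cldn2, a claudin, by log2 fold changes of 0.63 and -0.68 (0.0167 and 0.00235), Plxnb1, a semaphorin receptor, 2.24-fold and 1.54-fold (0.0068 and 0.0156), Gm7694 2.61-fold and 1.98-fold (0.0128 and 0.0125), and Pklr 2.02-fold and 1.69-fold (0.0137 and 0.0123). Chka, a choline kinase, fell 3.27-fold and rose 3.44-fold (0.0068 and 0.000569), and Zbtb16 7.06-fold and 5.90-fold (0.0068 and 0.000716). Sparc, a matrix glycoprotein, fell 1.90-fold and rose 2.41-fold (0.0184 and 0.000744), and Fos fell 3.59-fold and rose 11.4-fold (0.0377 and 0.00046). The clock genes Arntl and Npas2, picked here after their values were seen, were also opposite. Their log2 fold changes were -1.53 and 1.12, and -2.85 and 2.28. A difference in the hour of collection, taken up below, could give such changes and was not excluded. In model versus control, Fos lost its call in 9, Cldn2 in 5 and Sparc in 3 of 17 alternatives, each of them without any 1 of the 3 model libraries. Gm7694 lost both calls without model replicate 3 (highest adjusted p = 0.0552), and Plxnb1 that of treated versus model without model replicate 2 or treated replicate 2 (highest adjusted p = 0.0533).

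Across all 18113 genes, which are not independent replicates, the fold changes of model versus control and treated versus model had r = -0.137, against a mean of -0.501 (-0.558 to -0.458) in 100 data sets simulated without group effects, where the shared model libraries alone set the value. The covariance was -0.119, against -0.19 (SD 0.0128) simulated, a difference of 0.0704. Other splits of the real libraries gave covariances from -0.904 to -0.0876, a range far wider than that SD. Some lay above the observed value, among them -0.102 and -0.0896. The simulated SD therefore cannot show whether the difference goes beyond what regrouped libraries give, and no conclusion is drawn from it. With 1 model library held out for the comparison with treated livers and the other 2 compared with control, r was 0.0341, 0.0199 and 0.0643, with 7, 4 and 5 genes opposite and 19, 10 and 12 in the same direction. The count of same-direction genes was 49 with all libraries, 18, 18 and 14 without model replicate 1, 2 or 3, 25 and 22 without control replicate 2 or 3, and 29 with the replicate block, which had 33 opposite genes. More genes were thus opposite than in the same direction with that block, with limma-voom (35 and 34) and without model replicate 1 or 3. The count of opposite genes was 41 with all libraries and 12 without model replicate 2, 16 without model replicate 3, 19 without model replicate 1, 21 without control replicate 2 and 19 without control replicate 3, and r was -0.393, -0.422 and -0.387 without model replicate 1, 2 or 3, -0.213 without treated replicate 1 and -0.218 without treated replicate 3.

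Many named genes overlap another counted gene. On the same strand these are Gemin4, Lilr4b, Igsf23, Adgrv1, Npas2, Ugdh, Ephx1, Slc7a11, Per3, Vmn1r90, Gls2, Ndufb9 and Gm7694, and among those overlapped on the other strand are Plpp1, Stab2, Ccnd1, Hexa, Pklr, Egfr, Acaa1a, Usp18, G6pdx, Gpr146, Plxnb1 and Chka. Since use of strand is not stated, their values could hold reads of the partner.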

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

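Counts of called genes moved with the test and the threshold, and of 1921 values of named genes under other settings 1779 kept their direction and their side of the threshold, 142 lost the call and 0 changed direction. Lost calls touched 33 of 113 named results. In each sentence, counts are given as higher and lower for model versus control, then treated versus model, then treated versus control, and they were 94 and 108, 943 and 805, 1696 and 1535 as reported. With the replicate block they were 61 and 59 in model versus control, although same-numbered libraries did not covary (correlations -0.076 to 0.072), and the cause was not tested. With DESeq2 they were 453 and 415 in the first and 1481 and 1274 in the second comparison, and the cause was not tested. All 202 genes called in model versus control were among those of DESeq2. With log2(FPKM + 1), 66 were lower in the first, 1585 higher and 407 lower in the second, and 2704 higher and 689 lower in the third comparison. With log2(FPKM + 0.1), the corresponding counts were 62, 1509 and 408, 2670 and 693. FPKM carry no scaling for composition, and the median log2 fold change of all genes was 0.04, 0.12 and 0.16 in the 3 comparisons with log2(FPKM + 1), against -0.001, 0.005 and -0.009 with TMM. Without the filter on FPKM, 4 were higher and 2 lower in the first, 207 lower in the second and 610 lower in the third comparison. At an adjusted p under 0.01 the counts were 14 and 18, 356 and 222, 816 and 672. With an absolute log2 fold change of at least 1 they were 55 higher, then 531 and 219, then 912 and 542. Fewer genes can pass these 2 stricter thresholds by construction.

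Leaving out 1 library gave 28 to 112 higher and 26 to 119 lower genes in model versus control, 525 to 915 and 357 to 745 in treated versus model, and 1170 to 1631 and 999 to 1394 in treated versus control. The lowest values were those without model replicate 2, without model replicate 1 and without treated replicate 1, and groups of 2 libraries have less power. In treated versus model, 525 and 357 were called without model replicate 1, 540 and 432 without model replicate 3, 578 and 417 without treated replicate 1, and 617 and 476 without treated replicate 3. In model versus control they were 40 and 52 without control replicate 2, 40 and 42 without control replicate 3, 63 and 46 without model replicate 1, and 34 and 46 without model replicate 3. The lists called were 17, 28 and 29, with 16 to 22, 24 to 31 and 26 to 30 when 1 library was left out. With an estimated correlation they were 1, 5 and 0, as that setting allows for correlation within each list, and with fry 2 in model versus control.

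The 41 genes called in opposite directions were 139 with DESeq2, 5 at an adjusted p under 0.01, 19 with an absolute log2 fold change of at least 1, and 12 to 43 when 1 library was left out. They were 12, 19 and 16 without model replicate 2, 1 or 3, and 21 and 19 without control replicate 2 or 3. With model replicate 1, 2 or 3 alone compared with treated livers they were 7, 4 and 5, where the lone library is assumed to vary like the other groups. The correlation of -0.137 turned to 0.0341, 0.0199 and 0.0643 in those settings, in which the comparisons share no library, and ran from -0.422 to -0.155 when 1 library was left out, with -0.393 and -0.387 without model replicate 1 or 3. RLE and upper-quartile scaling, limma-voom and the other filters on counts kept the opposite count and the counts of called genes within 1.5 times of those reported. The fit of the groups compared and leaving out the 20 highest genes kept the counts of called genes within 1.5 times and were not run for the opposite count. The former ended the call of 7 of 113 named results. The correlation was -0.413 without a filter on low counts and -0.0134 with the filter on CPM, so it depended on the filter. Both lay within its jackknife standard error of 0.282 from the reported value. Leaving out a library also changed the filter, which then kept 18792 to 18907 genes against 18113. That error therefore mixes the filter with the spread between libraries and does not show the correlation to be stable. Libraries of one group differed far beyond counting error, and a limit set by depth was not tested.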

Other observations

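Macrophage markers differed among themselves, and the genes of this paragraph were chosen after their values were seen, apart from Mpeg1. Without model replicate 1, 5 of the 23 markers were called higher and 1 lower in treated versus model livers. In treated versus control livers, 8 were higher and 1 lower in that setting. Clec4f and Vsig4, markers of resident Kupffer cells, were at 102, 119 and 112 CPM and at 17.7, 20.7 and 20.8 CPM in control, model and treated livers, and neither passed the edgeR test in any comparison. Lyz2, a lysozyme of myeloid cells, was at 24.6, 40.4 and 261 CPM and rose 6.46-fold from model to treated livers (adjusted p = 0.00175). Itgax, an integrin of dendritic cells and of some macrophages, was at 0.661, 2.24 and 24.8 CPM and rose in treated versus model livers (adjusted p = 0.00383), as did Cd68, at 7.49 CPM in control and 54.3 CPM in treated livers, and Mpeg1 at 28.9, 52.2 and 183 CPM (adjusted p = 0.000346 and 5.59e-05). Slc40a1, the iron exporter, fell from 158 to 85.7 CPM (adjusted p = 0.00381). Of 14 neutrophil markers, 6 were called in treated versus control livers, each higher (9 adjusted over the list alone, adjusted p = 0.294 with an estimated correlation), with Lcn2 at 11.4, 70.7 and 609 CPM. Which cells expressed Lcn2 was not tested, so its level is no measure of neutrophils.

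Cholesterol synthesis and male-biased genes also differed between treated and control livers. Of 24 cholesterol synthesis genes, 12 were called, each higher (16 adjusted over the list alone, adjusted p = 0.412 with an estimated correlation), and 7 without model replicate 1. Of 26 male-biased liver genes, 11 were called, each lower (16 adjusted over the list alone, adjusted p = 0.125 with an estimated correlation), and 7 without model replicate 1. Of 18 stellate cell markers, 4 were higher and 5 lower in treated than in control livers. In treated versus model livers 3 were higher, Col1a1, Cygb and Nes, the last 2 named after their values were seen (3 adjusted over the list alone, camera adjusted p = 0.00296, and adjusted p = 0.328 with an estimated correlation), and 2 without model replicate 1.

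Of the tests below, those on muscle, endothelial and clock genes were chosen after the results were seen, and the counts of other splits were planned before. Skeletal muscle transcripts stood at 101 to 154 CPM in 4 libraries and at most 1.06 CPM in the other 5. Muscle tissue carried along with the liver sample is a candidate explanation, as 16 of 18 abundant muscle genes outside the fixed marker list were higher in each of the 4 libraries than in any other. Muscle RNA or reads that spread over these libraries at a later step would give the same, so this stays open. The 25 muscle genes, listed ones included, made up 0.0234 to 0.0322% of counts in the 4 libraries. No biological explanation was tested.

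Endothelial markers were lower in each model library than in each control library for 19 of 20 markers. A lower share of hepatocytes would raise markers of every other cell type alike if those types kept their proportions. In treated versus control livers, median log2 fold changes of -2.00 for endothelial and 0.84 for macrophage markers argue against it as the only change. A lower share together with shifts among other cell types stays open, and model livers were not tested in this way. On library totals alone the endothelial median was -1.38 in model versus control livers. TMM factors of these libraries, 0.905 to 0.998, lie too close together to shift that median much, so its outcome was set in advance. It shows only that the TMM factors did not make the fall. Fewer endothelial cells with unchanged transcripts stays open for model livers. The heterogeneity of the markers around 1 common change was 1.98 there, just under the bound of 2. In treated livers it was 8.24 and changes ran from -3.02 to -0.13, so 1 common fall does not describe the 20 markers. Falls can also be unequal where a marker is shared with other cells or only some endothelial cells are lost. Fewer endothelial cells thus stays open in treated livers too. Stellate cell markers, with a median of -0.56 in model versus control livers, lay lower as well. A yield of cells that differs between groups, as the samples are titled liver cells, and a change of transcription within these cells under the model condition may both add to it and were not tested.

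In model versus control livers, the fold changes of all 16 clock genes of 2 antiphase arms pointed apart, though only 3 of the 16 were called. Medians were -1.51 for the early and 1.40 for the late arm. In treated versus control livers, which share no model library, the 5 early genes were lower. The late genes went both ways there, 5 higher and 6 lower (medians -0.45 and -0.05). In treated versus model livers, the 5 early genes were higher and 10 of 11 late genes lower (medians 1.06 and -0.75), with 5 called. That comparison shares the model libraries, which favours the reverse direction. Collection of the model livers at another hour of the day is a candidate explanation for the clock genes, as these 16 go with it. Genes that follow the clock could then be among those called in both comparisons with model livers, and among the genes called in opposite directions. The late minus early difference was -1.41 to -0.44 in control, 1.18 to 2.09 in model and -1.21 to 0.71 in treated libraries, with treated replicate 2 at 0.71 apart from the other treated libraries. The labels give no hour, so an effect of the model condition on the clock stays open, untested.

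The splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In model versus control, 202 genes were called, against at most 2 in the other splits, and 17 lists against at most 23, so that 2 of the 10 splits gave as many lists, and in each other case the real split, 1 of 10, gave most. In treated versus model these were 1748 genes against 1 and 28 lists against 26, and in treated versus control 3231 genes against 1 and 29 lists against 26. Each other split mixes the 2 real groups, so any difference between them widens the spread within the new groups. Few gene calls in such splits were therefore set in advance, whatever made the groups differ, and they add no support. Among 100 splits of the 9 libraries into 3 groups, 2 gave as many genes in opposite directions as the real 41, a share under 0.05. These were the real split and 1 other. Apart from these, regrouped libraries gave at most 7 such genes, as mixed groups seldom yield calls. This count therefore does not separate the grouping of control and model libraries from others. The other split had 996 such genes, kept the 3 treated libraries together and mixed control with model libraries, and so points to the structure of the samples. For the correlation of -0.137, 1 of 100 splits, the real one, was as high, the highest other being -0.152. The covariance of -0.119 was exceeded in other splits, among them those at -0.0876, -0.0896 and -0.102. The other splits relabel libraries of the real groups and so carry the differences between them. They are no reference without group effects, and no conclusion on the correlation or the covariance is drawn from them.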
